A study of Mus musculus with 8 samples.

How the data were processed

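RNA was measured with whole-transcript expression arrays in the suprachiasmatic nucleus (SCN), the hypothalamic cell group that holds the master circadian clock of mammals. Per the labels, the mice were C57BL/6J wild type or lacked Gpr176, had been kept on a cycle of 12 h light and 12 h dark for more than 2 weeks, and were sampled in constant darkness at circadian time 6 (CT6, subjective day) or 18 (CT18, subjective night). Per the labels' protocols, the SCN was taken by laser microdissection and tissue from 10 animals was pooled for each array, so the 8 arrays stand for 80 animals and the 2 arrays of each of the 4 groups are separate biological pools. The labels' protocols name column purification of the RNA, a whole-transcript amplification kit and biotin labelling.

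The authors deposited 1 table of log2 values with 28853 probes and 8 arrays. How the scanner signals were corrected for background, summarised and normalized is not given in the sources used here. The deposited medians lay between 7.34 and 7.39, the minimum values near 4.74 and the maximum values near 14.2. The lower quartiles of the arrays spread over 0.139, the medians over 0.0504 and the upper quartiles over 0.0890 on the log2 scale. The rule set in advance asked for quantile normalization where any quartile spread by more than 0.1, and the lower quartiles did, so the 8 columns were quantile normalized with limma. This step gives every array the same distribution and would hide a change shared by most genes. The values as deposited and values centred on each array's median were carried along as alternatives.

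Probes were named from the annotation of the array platform. It listed 23410 of the probes, 21789 with exactly 1 gene symbol and 1621 with several, and 5443 probes were unnamed here. Of the probes with 1 symbol, 21698 were matched by Entrez number to the RefSeq table of assembly GRCm38.p6, and 0 symbols changed through that match. That table served for gene names and, through the order of its positions, for which genes neighbour each other. None of its coordinates is printed. For each of 19938 genes the probe with the highest mean over the 8 arrays was used, which mattered for 999 genes with more than 1 probe. Genes whose mean lay under the 40th percentile of all probes, a log2 level of 6.82, were left out. That removed 7486 genes and left 12452 for testing.

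A linear model with a mean for each group was fitted to all 8 arrays in limma 3.58.1 under R 4.3.3, leaving 4 residual degrees of freedom, with variances moderated across genes (prior degrees of freedom 5.58). From this fit 7 contrasts were taken, which were CT18 against CT6 in each genotype and over both, knockout against wild type at each time and over both, and the difference of the day-night change between genotypes (the interaction). Adjusted p-values are from limma with the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. Values after ± are the standard errors of the fit unless an SD is named. The number of arrays, 2 per group, limits the precision. The median standard error was 0.0636 on the log2 scale for a contrast of 2 groups, 0.0449 for a contrast over both genotypes or times and 0.0899 for the interaction.

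In simulated data with 200 changed genes, the limma fit and its adjustment were tested over 20 draws. Noise was drawn independently for each gene, with the moderated variances of the real fit as the true ones. Normalization, probe choice and the level filter were not simulated, nor were array differences shared across genes. The shares below therefore need not hold for the real arrays. For the wild-type day-night contrast 41.1% of genes changed by 0.25 log2 were recovered, 98.4% of those changed by 0.5 and 100% of those changed by 1. For the knockout contrast over both times 86.1% of genes changed by 0.25 were recovered and 100% at 0.5, and for the interaction 6.79%, 83.1% and 99.8% at the 3 sizes. Between 6.72% and 7.28% of the calls were false in these draws, somewhat above the nominal 5%.

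For each contrast, 23 gene lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists. Camera with an estimated correlation and fry stand beside it, as do counts of members past the threshold over the genes tested and adjusted over the list alone. The comparisons, the normalization rule, the filter, the lists, most other settings and the rule for genes to name were set before the data were examined. That rule always names Gpr176, Gnaz, Rgs16, Per1, Per2, Arntl, Nr1d1, Dbp, Avp, Vip and Prok2. It adds, per contrast, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, and up to 4 called members of each list by smallest p. Where fewer than 5 genes were called it takes the 5 smallest p. Genes with only a provisional symbol (such as Gm or Rik), and those of the Mir, Snor, Olfr and Vmn families, were not named under it. Some genes were named outside the rule, after their values were seen: Dusp10, Dusp16, Dusp7, St8sia6, St3gal1, St8sia2, Wnt5a, Sfrp2, Dkk2, Drd5, Nr4a2, Nr4a3, Rasd2, Bhlhe41, Nr1d2, Per3, Vipr2, Mtnr1a, Cirbp, Rbm3, Adcy1, Rgs20, Fos, Gem, Cry2, Csnk1e, Nampt, Rorb, Wee1, Pde7b, Six3, Egr1, Gadd45b, Nmu, Rgs2, Hspb1, Ddc and Slc18a2 for the day-night change over both genotypes, Rgs2 for that of wild type, Hspb1 for the interaction, and Nms, Gal, Oxt, Th, Gria3, Gabra2 and Fsip1 between genotypes. So were 7 leptomeningeal genes, named where their values are given.

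The other settings chosen in advance were median centring, no filter and a filter at the 60th percentile, the mean of a gene's probes, all probes, moderation with a trend and robust variances, an adjusted p under 0.1, a minimum change of 1.5-fold, the replicate letter as a block, array weights, a fit of only the groups compared, and leaving out each array in turn. The values as deposited, a crossed block, a covariate for an axis of array differences and lists with Gpr176 left out were added after the data had been seen.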

Results

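Transcript levels were compared in the SCN of wild-type and Gpr176 knockout mice at CT6 and CT18 in constant darkness. Gpr176 encodes an orphan G protein-coupled receptor of SCN neurons that couples to Gz. Each of the 4 groups had 2 arrays, A and B, and each array carried RNA pooled from 10 animals. The deposited log2 medians of the arrays were 7.35 and 7.36 for wild type at CT6, 7.34 and 7.36 for wild type at CT18, 7.39 and 7.35 for the knockout at CT6 and 7.37 and 7.38 for the knockout at CT18. The arrays of a group correlated at r = 0.998, 0.997, 0.996 and 0.997 over probes in the same order, which describes probes and not independent replicates. The first principal component held 51.9% of the variance and separated CT18 from CT6. The next held 18.1% and was led by wild type at CT18 A (score 9.17) and knockout at CT18 A (score -8.85).

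Gpr176, the targeted gene, was lower in each knockout array than in each wild-type array. Its log2 level was 9.37 and 9.31 in wild type at CT6 and 9.73 and 9.87 in wild type at CT18, against 8.08 and 8.02 in the knockout at CT6 and 8.42 and 8.56 at CT18. The difference was -1.30 ± 0.0491 over both times (limma adjusted p = 3.37e-06), -1.30 ± 0.0694 at CT6 (adjusted p = 9.28e-05) and -1.31 ± 0.0694 at CT18 (adjusted p = 8.38e-05). Gpr176 also rose from CT6 to CT18, by 0.46 log2 in wild type (adjusted p = 0.00436) and by 0.44 in the knockout (adjusted p = 0.00507). A signal thus remained in the knockout arrays, and the labels do not say which part of the gene was deleted or where the probe lies relative to it.

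**Figure D1:**
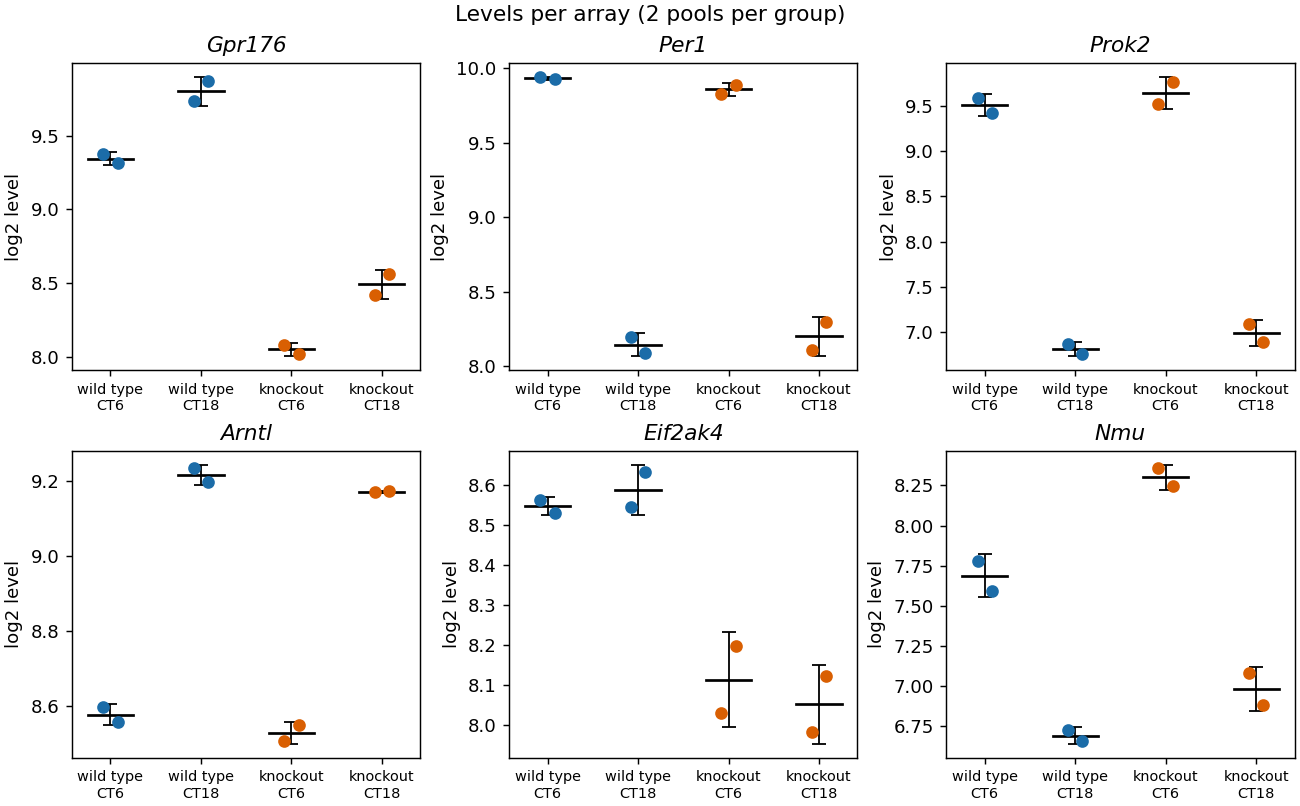
Log2 level (vertical axis) of Gpr176, Per1, Prok2, Arntl, Eif2ak4 and Nmu in the 4 groups; points are arrays, lines the group means and bars the SD (n = 2). Gpr176 lies at 8.02 to 8.56 in the knockout and 9.31 to 9.87 in wild type, while Per1, Prok2 and Arntl separate by circadian time in both genotypes.

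The wild-type comparison asked which transcripts differ between subjective night and subjective day in the clock itself. The largest falls at CT18 were those of Prok2, a secreted peptide that carries SCN output (-2.70 ± 0.0994), Rasl11b, a Ras-like GTPase (-2.33 ± 0.0762), Dusp4, a phosphatase of MAP kinases (-2.13 ± 0.101), and Ciart, a repressor within the clock (-2.07 ± 0.0840). Core clock genes of the day phase fell with them, including Per1 (-1.79 ± 0.0709), Per2 (-1.55 ± 0.0911), Dbp, a PAR bZIP transcription factor (-1.61 ± 0.0850), and Nr1d1, the repressor REV-ERBα (-1.10 ± 0.0686). Arntl, which encodes the activator BMAL1, rose by 0.64 ± 0.0514. The largest rises were those of Rasd1, a dexamethasone-inducible Ras protein (1.59 ± 0.0644), Tuba8, an alpha-tubulin (1.40 ± 0.0673), Avpr1a, the V1a vasopressin receptor (1.30 ± 0.0725), and Sertm1 (1.25 ± 0.0736). Limma adjusted p-values for these genes ran from 8.36e-07 for Rasl11b to 8.96e-05 for Arntl.

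Further strong falls were those of Creb3l1, a transcription factor of the endoplasmic reticulum (-1.59), Rgs16, a regulator of Gi-class G protein signalling (-1.45), Chrna3, a nicotinic receptor subunit (-1.40), Fbxl21, an F-box protein acting on cryptochromes (-1.40), Vgf, a neuropeptide precursor (-1.19), and Avp, the vasopressin precursor (-0.94). Dnajb1, a heat shock cochaperone (1.03), Fzd8, a Wnt receptor (0.98), Prkg2, a cGMP-dependent protein kinase (0.98), Nfil3, a repressor of D-box genes (0.96), Tarsl2, a threonyl-tRNA synthetase (0.95), and Pcdh18, a protocadherin (0.92), rose. Over both genotypes, a second probe of Prkg2 gave 0.32 where the one used gave 0.92. The mean log2 level of the second probe, 5.90, lay under the filter of 6.82. Of 53 genes of G protein and cAMP signalling 7 rose and 7 fell (9 and 8 adjusted over the list alone; camera adjusted p = 0.919). The phosphodiesterases Pde10a (-0.76) and Pde4d (-0.61) and the G protein subunit Gnb4 (-0.53) fell. Rgs2, a regulator of G protein signalling, rose (0.33), but did not pass without wild type at CT6 B or CT18 B (highest adjusted p 0.0671). Gnaz, the Gz alpha subunit, differed by 0.11 ± 0.0701 (adjusted p = 0.387) and Vip, a neuropeptide of the SCN core, by 0.04 ± 0.0558 (adjusted p = 0.702), and neither passed the test.

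In all, 548 genes were higher and 316 lower at CT18 in wild type, or 6.94% of 12452. Of these, 55 of the higher and 62 of the lower genes differed by at least 1.5-fold. Among the fixed lists, the day-phase clock genes fell (0 of 15 higher, 12 lower, and 13 lower adjusted over the list alone; camera adjusted p = 3.27e-24). This was the single list of the contrast that also passed with an estimated correlation (adjusted p = 0.0424). CRE-driven and immediate early genes fell as a list (3 of 22 higher, 11 lower; 5 and 13 adjusted over the list alone; adjusted p = 4.69e-05; adjusted p = 0.380 with an estimated correlation). Sik1, a salt-inducible kinase (-1.06), the orphan receptor Nr4a1 (-0.98) and Dusp1, a MAP kinase phosphatase (-0.92), fell. Npas4, an activity-induced transcription factor (0.75), rose. Heat shock genes rose (10 of 18 higher, 2 lower; 14 and 3 adjusted over the list alone; adjusted p = 5.98e-07; adjusted p = 0.10 with an estimated correlation), among them Dnajb1, Hspb1 (0.80) and Hsph1 (0.70). Endoplasmic reticulum folding genes, led by Sdf2l1 (0.70), rose as a list (6 of 23 higher, 2 lower; 11 and 2 adjusted over the list alone; adjusted p = 0.0215; adjusted p = 0.397 with an estimated correlation). By camera alone, the sterol synthesis list was called higher (3 of 17 higher, 0 lower; 5 and 0 adjusted over the list alone; adjusted p = 0.0455) and the oligodendrocyte list lower (0 of 12 higher, 1 lower; 0 and 2 adjusted over the list alone; adjusted p = 0.0138). Each of these 2 lists had an adjusted p of 0.828 with an estimated correlation. By fry, which tests whether the genes of a list move on balance one way, the sterol (adjusted p = 0.143) and oligodendrocyte lists (0.498) did not pass. Fry also called the clock activators and night-phase clock genes, which camera did not. The sterol call was lost without wild type at CT6 A or CT18 A or knockout at CT6 A or B, and with the array axis as a covariate. The oligodendrocyte call was lost without wild type at CT6 B or CT18 B, and the folding call without wild type at CT18 B, which left between 4 and 6 lists. Leaving out 1 array lowered the count of 864 genes to 382 without wild type at CT6 A, 368 without CT6 B, 311 without CT18 A and 486 without CT18 B.

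In the knockout the same question was asked of animals without Gpr176. Prok2 (-2.65 ± 0.0994 on the log2 scale), Dusp4 (-2.30 ± 0.101), Rasl11b (-2.22 ± 0.0762) and Ciart (-1.99 ± 0.0840) had the largest falls at CT18. Per1 (-1.66 ± 0.0709), Per2 (-1.40 ± 0.0911), Dbp (-1.49 ± 0.0850) and Nr1d1 (-1.03 ± 0.0686) fell as well, and Arntl rose by 0.64 ± 0.0514. Rasd1 (1.54), Tuba8 (1.39), Avpr1a (1.28) and Sertm1 (1.13) were again the largest rises. Limma adjusted p-values of these genes ran from 1.08e-06 for Prok2 to 8.28e-05 for Arntl.

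Creb3l1 (-1.39), Rgs16 (-1.35), Fbxl21 (-1.35), Nmu, the neuropeptide neuromedin U (-1.32), Nr4a1 (-1.23) and Avp (-0.87) also fell in the knockout. Fzd8 (0.98), Tarsl2 (0.98), Dnajb1 (0.95), Ociad2 (0.94), Prr15 (0.90), Hs3st1, a heparan sulfate sulfotransferase (0.90), Slc6a3, the dopamine transporter (0.77), and Nfil3 (0.73) rose. The list members that passed included Rgs2 (0.53), the calcium channel Cacna1c (0.41), the potassium channel Kcnc2 (-0.58), and Fabp7, a fatty acid binding protein of astrocytes (-0.83). Gnaz (0.15 ± 0.0701, adjusted p = 0.257) and Vip (0.14 ± 0.0558, adjusted p = 0.162) did not pass.

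The knockout had 452 genes higher and 439 lower at CT18, or 7.16% of 12452, with 45 and 62 of them changed by at least 1.5-fold. Day-phase clock genes fell (0 of 15 higher, 11 lower, and 13 lower adjusted over the list alone; camera adjusted p = 8.14e-20). This call was lost with an estimated correlation (adjusted p = 0.0621). CRE-driven and immediate early genes also fell as a list (3 of 22 higher, 10 lower; 6 and 11 adjusted over the list alone; adjusted p = 0.00277; adjusted p = 0.535 with an estimated correlation). By camera alone, with 1 member passing in each, the oligodendrocyte list (0 of 12 higher, 1 lower; 0 and 2 adjusted over the list alone; adjusted p = 0.0124) and the endothelial and mural list were called lower (0 of 11 higher, 1 lower; 0 and 1 adjusted over the list alone; adjusted p = 0.0124). Each of these 2 had an adjusted p of 0.750 with an estimated correlation. Heat shock genes rose as a list (9 of 18 higher, 0 lower; 11 and 2 adjusted over the list alone; adjusted p = 7.15e-06; adjusted p = 0.136 with an estimated correlation). So did endoplasmic reticulum folding genes (5 of 23 higher, 1 lower; 8 and 2 adjusted over the list alone; adjusted p = 0.00717; adjusted p = 0.368 with an estimated correlation). By camera alone the sterol synthesis list was called higher (3 of 17 higher, 0 lower; 5 and 0 adjusted over the list alone; adjusted p = 0.0300; adjusted p = 0.750 with an estimated correlation). By fry the sterol (adjusted p = 0.205), oligodendrocyte (0.333) and endothelial lists (0.226) did not pass. Fry also called the clock activators with night-phase clock genes and the SCN identity genes, which camera did not. The oligodendrocyte and endothelial calls were lost without knockout at CT6 A and the sterol call without knockout at CT6 B or CT18 B, which left 6, 7 and 6 lists called. Leptomeningeal genes were measured beside them, in 2 lists chosen after values were seen. CT18 minus CT6 in the knockout was -0.78 (standard error over arrays 0.578) for 7 genes and -0.23 (0.213) for 20 others. The mean log2 level of the 7 was 9.07 in knockout at CT6 A and 8.23 at CT6 B, against 7.85 and 7.88 at CT18. Leaving out 1 array lowered the count of 891 genes to 438 without knockout at CT6 A, 508 without CT6 B, 382 without CT18 A and 392 without CT18 B. Median centring lowered it to 590, with 274 higher and 316 lower.

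**Figure D2:**
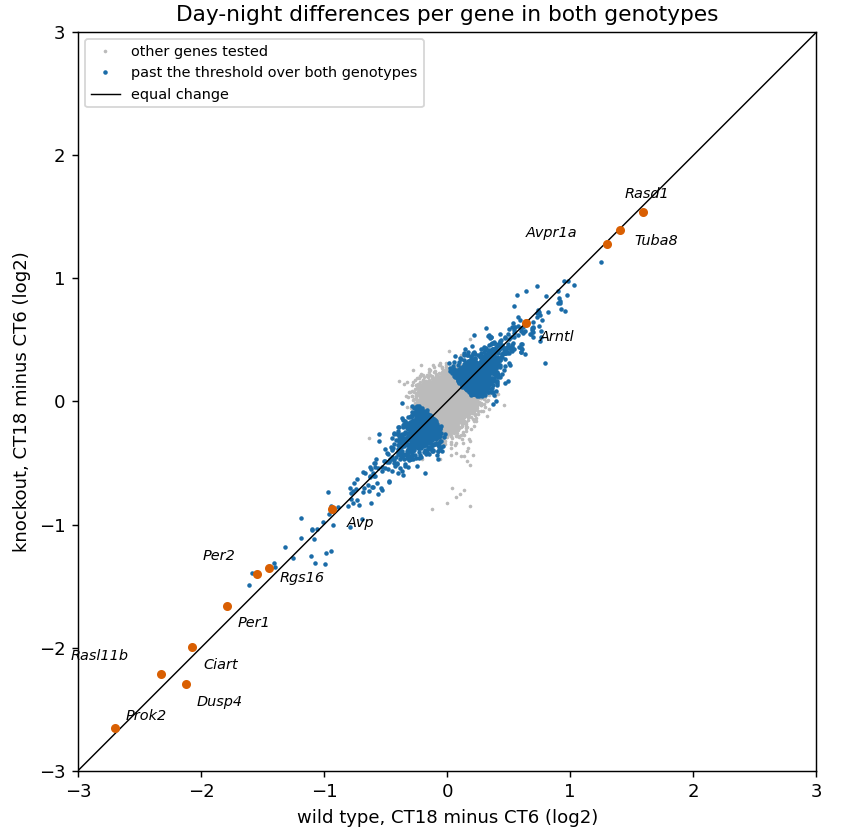
Log2 change from CT6 to CT18 per gene in wild type (horizontal axis) and in the knockout (vertical axis); blue points are the 2096 genes called over both genotypes, the diagonal marks equal change and 12 genes are labelled. Prok2 lies at -2.70 and -2.65, Rasd1 at 1.59 and 1.54, and the changes correlate at r = 0.756 over 12452 genes.

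Over both genotypes, with 4 arrays at each time, the rhythm of the clock genes was seen with the smallest error. Of 15 day-phase clock genes tested 13 fell, from Ciart (-2.03), Per1 (-1.72), Dbp (-1.55) and Per2 (-1.48) to Cry2 (-0.17), and Nampt (-0.01) and Wee1 (-0.04) did not pass. Cry2 did not pass with median centring (adjusted p = 0.0502). Bhlhe41 (-1.25), Nr1d2 (-1.07) and Per3 (-0.62) were among them. Of the 10 activators and night-phase clock genes, 2 rose, Nfil3 (0.84) and Arntl (0.64), and 4 fell, Fbxl21 (-1.37), the nuclear receptors Rora (-0.83) and Rorb (-0.39), and the kinase gene Csnk1e (-0.19). In total 1250 genes were higher and 846 lower at CT18, or 16.8% of those tested. Without knockout at CT18 B the count of 2096 fell to 1385.

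Neuropeptide genes and their receptors moved in both directions. Of 28 tested, 6 fell, including Prok2 (-2.67), Nmu (-1.16), Vgf (-1.07) and Avp (-0.90). Another 8 rose, including Avpr1a (1.29), the VIP receptor Vipr2 (0.62) and the melatonin receptor Mtnr1a (0.61). Vip itself was at 0.09 ± 0.0394 (adjusted p = 0.139) and did not pass. The camera test gave adjusted p = 0.770, and the median of the list (0.0310) lay above 0 while its mean (-0.0902) and the direction of the test were negative. Of 19 SCN identity genes, 5 rose, including Gpr176 (0.45) and the LIM transcription factor Lhx1 (0.38), and 5 fell, including Rgs16 (-1.40) and Six3 (-0.22). Six3 kept its call only when the 1 array left out was wild type at CT6 B or CT18 B or knockout at CT6 A. The camera adjusted p of the identity list was 0.571, with a median of 0.0315 and a mean of -0.0822. Of 53 G protein, RGS and cAMP genes, 10 rose and 10 fell. Adcy1, an adenylyl cyclase (0.38), Rgs2 (0.43) and the phosphodiesterase Pde7b (0.43) were among the rising genes. Pde10a (-0.75), Gnb4 (-0.63), Pde4d (-0.58) and Rgs20 (-0.38) were among the falling ones. Their camera adjusted p was 0.856, with a test direction and median (0.0305) above 0 and a mean of -0.0168. Gnaz stood at 0.13 ± 0.0496 (adjusted p = 0.108). Adjusted over the list alone, the higher and lower counts of the activators were 3 and 5, of the neuropeptides 8 and 6, of the identity genes 5 and 5, and of the G protein genes 14 and 11. The activators had a camera adjusted p = 0.302, with a median of -0.0766.

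CRE-driven and immediate early genes fell as a list, with 12 of 22 lower and 5 higher (adjusted over the list alone, 12 and 6; camera adjusted p = 0.000501; adjusted p = 0.401 with an estimated correlation). The falling members were led by the orphan receptors Nr4a1 (-1.11), Nr4a3 (-0.90) and Nr4a2 (-0.50), Sik1 (-1.05), Dusp1 (-0.96), Fos (-0.66) and Gem (-0.64). Npas4 (0.62), Gadd45b (0.55) and Egr1 (0.37), also activity-induced, rose. Heat shock and temperature-responsive RNAs rose, with 13 of 18 higher and 2 lower (adjusted over the list alone, 13 and 3; adjusted p = 1.91e-06; adjusted p = 0.115 with an estimated correlation). Dnajb1 (0.99), Chordc1 (0.71), Hsph1 (0.63) and Hspb1 (0.55) led them, and the 2 that fell were the cold-inducible RNA-binding proteins Cirbp (-0.30) and Rbm3 (-0.30). Endoplasmic reticulum folding genes rose, with 9 of 23 higher and 2 lower (adjusted over the list alone, 11 and 2; adjusted p = 0.00432; adjusted p = 0.343 with an estimated correlation). Sdf2l1 (0.67) and the chaperone Hspa5 (0.30) rose and Herpud1 (-0.39) fell. The sterol synthesis list was called higher by camera with 7 of 17 higher and 0 lower, also adjusted over the list alone (adjusted p = 0.0238; adjusted p = 0.827 with an estimated correlation), among them Sqle (0.31), squalene epoxidase, and Fdft1 (0.28), squalene synthase. Of the calls in this paragraph the sterol list's was lost without wild type at CT6 A or CT18 A or knockout at CT6 B or CT18 B, where 7, 6, 6 and 5 lists were called. By fry the immediate early, heat shock and folding lists passed, and the sterol list did not (adjusted p = 0.0569). Fry also called the day-phase clock, activator, neuropeptide, identity, glucocorticoid-responsive and blood cell lists.

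Channel genes had 10 of 40 members higher and 4 lower (14 and 5 adjusted over the list alone; camera adjusted p = 0.0521; adjusted p = 0.827 with an estimated correlation), with the calcium channel Cacna1c (0.44) and the potassium channel Kcnd3 (0.36) up and Kcnc2 (-0.59) down. Camera called this list with no filter and without wild type at CT6 A or knockout at CT6 B or CT18 A. GABA and glutamate genes had 9 of 34 higher and 5 lower (12 and 6; adjusted p = 0.668), including the NMDA receptor subunit Grin2b (0.44) and the GABA receptor subunit Gabre (-0.31). Glucocorticoid-responsive genes had 5 of 13 higher and 1 lower (8 and 2; adjusted p = 0.261), with Ddit4 at 0.32 and the metallothionein Mt2 at -0.26. Mitochondrial respiratory chain genes had 2 of 41 higher and 0 lower (1 and 0; adjusted p = 0.906; median 0.0147 and mean 0.0109 against a negative test direction). Synaptic vesicle genes had 3 of 26 higher and 4 lower (3 and 4; adjusted p = 0.261), with the scaffold gene Shank1 at 0.31 and the release genes Syt5 (-0.26) and Syt4 (-0.21) lower. The mitochondrial genes were Ndufa2 (0.26) and Cyc1 (0.14), and Cyc1 kept its call only when the 1 array left out was wild type at CT6 A or CT18 A. The pairs in brackets are the counts adjusted over the list alone.

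Markers of cells that a dissection of the SCN could also hold were counted in the same way. The oligodendrocyte list was called lower at CT18 by camera (adjusted p = 0.00432; adjusted p = 0.827 with an estimated correlation), with 2 of 12 lower, Opalin (-0.66) and Ugt8a (-0.45), and 0 higher, a call lost without wild type at CT18 B or knockout at CT6 A, where 5 lists passed, and by fry (adjusted p = 0.261). Astrocyte markers had 2 of 14 higher and 2 lower (adjusted p = 0.668; median 0.00714 and mean -0.0500), with Fabp7 at -0.72 and the connexin Gjb6 at 0.22. Of the endothelial and mural markers 2 of 11, Tek (-0.24) and Pdgfrb (-0.20), were lower and 0 higher (adjusted p = 0.105; adjusted p = 0.827 with an estimated correlation). Camera called this list with no filter and without wild type at CT6 A or CT18 A. Tek did not pass without wild type at CT6 B (adjusted p = 0.0526), nor Pdgfrb without wild type at CT6 B or CT18 B or knockout at CT6 A or CT18 A (highest 0.0831). Of the ependymal and tanycyte markers Hdc (0.41) was higher and Rarres2 (-0.23) and Ccdc153 (-0.21) lower among 12 (adjusted p = 0.438), and of 3 choroid plexus markers Folr1 (-0.21) was lower (adjusted p = 0.584). The 1 blood cell marker tested, Alas2 (-0.18), was lower (adjusted p = 0.248). It kept its call only when the 1 array left out was wild type at CT6 A or CT18 B or knockout at CT18 A. Neighbouring hypothalamic neuron markers had 2 of 12 higher, Slc6a3 (0.66) and Gnrh1 (0.22), and 0 lower (adjusted p = 0.886; median -0.0165 and mean 0.0386). Gnrh1 kept its call only when the 1 array left out was wild type at CT18 A or knockout at CT18 B. With limma, 0 of 11 microglia markers (adjusted p = 0.856; median -0.00859 and mean 9.28e-05) and 0 of 3 sex-linked markers (adjusted p = 0.518) passed, with 3 and 1 at an unadjusted p under 0.05. The counts of each of these marker lists were the same adjusted over the list alone.

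**Figure D3:**
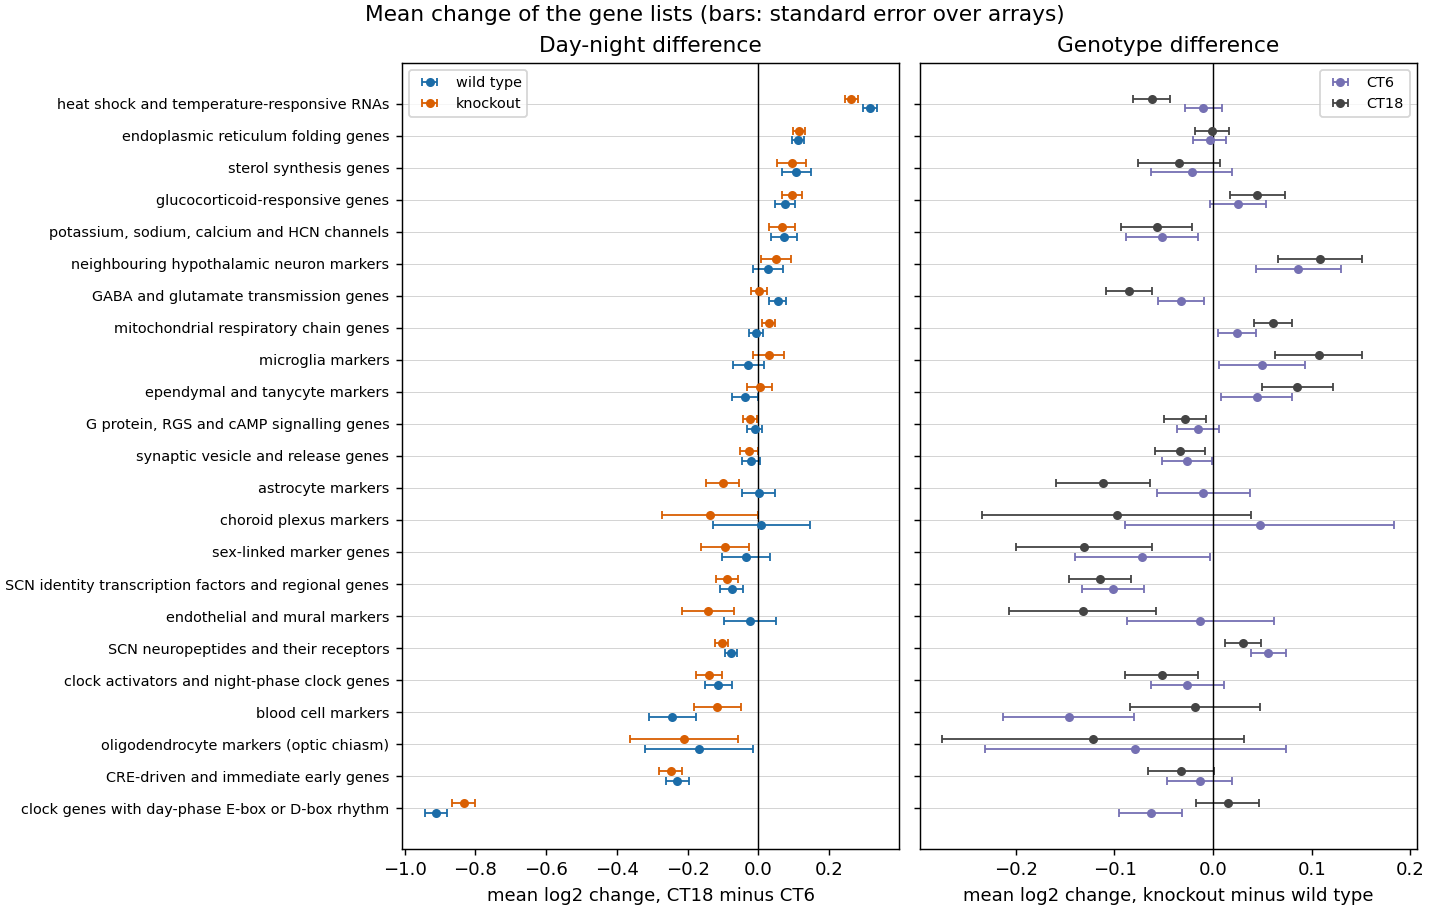
Mean log2 change of the genes of each fixed list, with the standard error over arrays as bars; the left panel gives CT18 minus CT6 in wild type and in the knockout, the right panel knockout minus wild type at CT6 and at CT18. Over both genotypes the mean of the day-phase clock genes is -0.872 and that of the heat shock genes 0.289, while the means between genotypes stay near 0 (the SCN identity list includes Gpr176).

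The next comparison asked whether loss of Gpr176 altered the day-night difference. Per1 differed between the genotypes in its day-night change by 0.13 (95% interval -0.09 to 0.35), Per2 by 0.15 (-0.14 to 0.43), Prok2 by 0.05 (-0.27 to 0.36) and Arntl by 0.00 (-0.16 to 0.17). For Gnaz the value was 0.03, for Rgs16 0.09, for Nr1d1 0.06, for Dbp 0.11, for Avp 0.06, for Vip 0.10 and for Gpr176 itself -0.01. The smallest p-values belonged to Prp2 (0.49, unadjusted p = 0.000500), the protocadherin Pcdhb10 (-0.55, 0.000598), Efcab10 (-0.39), Aph1b, a gamma-secretase subunit (-0.40), and Arc, an activity-regulated synaptic gene (0.34), each at an adjusted p of 0.944. Limma called 0 genes, and 605 had an unadjusted p under 0.05. Adjusted over the list alone, Arc (0.0282) among the immediate early genes and Hspb1 (-0.49; 0.0343) among the heat shock genes passed.

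The day-night changes of the genotypes were set against each other directly. Wild type and knockout shared 312 called genes higher at CT18, against 19.9 for independent lists, and 219 lower, against 11.1. Both contrasts use the same estimate of spread for a gene, so their calls are not independent and these expected numbers may be too low. No gene was called in opposite directions. Of the genes called in wild type, 540 of 548 and 305 of 316 had the same sign in the knockout. Over 12452 genes the changes correlated at r = 0.756 and Spearman's rho = 0.562, a relation across genes, which are not independent replicates. For the 2096 genes called over both genotypes the 95% interval of the interaction lay within 2-fold either way for 2096 and within 1.5-fold for 2085. Only 51 of the higher and 62 of the lower genes among them changed by 1.5-fold or more between CT18 and CT6. For most of the 2096 genes these bounds were thus wider than the change itself and cannot show that it was kept. Of these genes 119 (5.68%) had an unadjusted interaction p under 0.05. Only 2 times were sampled, so amplitude and phase of a rhythm cannot be told apart. The 2096 genes were picked for their change over both genotypes, which disfavours genes changed in only 1 genotype. Opposite genotype effects can also cancel in a mean over genes. The mean day-night difference of these genes, signed by direction over both genotypes, was 0.270 log2 in wild type and 0.272 in the knockout. The knockout value was 100.6% ± 4.14 (standard error in percentage points) of that of wild type. A two-sided exact permutation test over 36 assignments gave p = 1, where the design allows no p under 0.0556.

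By camera, 2 lists differed in their day-night change between genotypes. The day-phase clock genes had a median interaction of 0.0770, with 0 of 15 members passing in limma, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05 (adjusted p = 0.0432; adjusted p = 0.905 with an estimated correlation). Astrocyte markers had a median of -0.0992, with 0 of 14 passing, 0 adjusted over the list alone and 1 at an unadjusted p under 0.05 (adjusted p = 0.0432; adjusted p = 0.905 with an estimated correlation). With the values as deposited both stood at an adjusted p of 0.0990, with median centring at 0.105, and fry and the fit with a replicate block called 0 lists. The clock call was lost without wild type at CT6 B or CT18 A or knockout at CT6 A, CT18 A or CT18 B, and the astrocyte call without wild type at CT6 A or CT18 A or knockout at CT6 A or CT18 A and with the array axis as a covariate. Leptomeningeal genes, in the lists chosen after values were seen, stood at -0.84 (standard error over arrays 0.817) for 7 genes and -0.29 (0.301) for 20 others in the same contrast. The mean log2 level of the 7 was highest in knockout at CT6 A (9.07) and wild type at CT18 A (9.02). Removal of either array ended both calls, but so did removal of knockout at CT18 A, where the level was 7.85. Removal of wild type at CT6 B (8.74) ended the clock call only. The number of lists called was 0 without knockout at CT18 A, 1 without wild type at CT6 A and 5 without wild type at CT18 B.

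Knockout and wild type were last compared in level. Over both times 3 genes passed, each lower in the knockout. Beside Gpr176 these were Eif2ak4, the kinase GCN2 that senses amino acid shortage (-0.48 ± 0.0516, adjusted p = 0.0240), and Tmem185b, a membrane protein (-0.40 ± 0.0473, adjusted p = 0.0425). The next smallest p-values were those of Nmu (0.45 ± 0.0600, adjusted p = 0.0705) and Mid1, a ubiquitin ligase (-0.41 ± 0.0551, adjusted p = 0.0705). In each of the 4 knockout arrays Eif2ak4 lay below each of the 4 wild-type arrays. Eif2ak4 is the nearest protein-coding neighbour of Gpr176 on 1 side in assembly GRCm38.p6.

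Clock and output genes differed little in level between genotypes. Over both times the difference was -0.01 for Per1, -0.05 for Per2, -0.05 for Arntl, -0.01 for Nr1d1, -0.01 for Dbp, 0.03 for Rgs16, 0.04 for Gnaz, 0.05 for Vip, 0.16 for Prok2 and 0.17 for Avp, with adjusted p-values from 0.342 for Avp to 0.979 for Dbp. None of these 10 passed. Of 12452 genes, 1496 had an unadjusted p under 0.05. Eif2ak4 no longer passed without wild type at CT6 A, CT6 B or CT18 B, or knockout at CT6 A or CT18 A, with values from -0.53 to -0.44 over the arrays left out and a highest adjusted p of 0.223. Without any 1 of these 5 arrays only 1 gene, Gpr176, passed. Tmem185b kept its call only when the 1 array left out was knockout at CT18 B (-0.44), and Mid1 (-0.47) passed without wild type at CT18 A. With no filter Eif2ak4 (adjusted p = 0.0684) and Tmem185b (0.110) did not pass. With the values as deposited 2 genes were higher and 4 lower, and with median centring 1 and 4.

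At CT6 only Gpr176 passed, with 0 genes higher, and 528 genes had an unadjusted p under 0.05 in limma. Nmu (0.61 ± 0.0849, adjusted p = 0.217), Mid1 (-0.46, 0.536), Eif2ak4 (-0.43, 0.536) and Podn (0.25) came next, Podn with the highest adjusted p of these. Nmu passed with the values as deposited (0.63, adjusted p = 0.0454) and with median centring (0.61, adjusted p = 0.0285), where 1 gene was higher and 1 lower. At CT18 Gpr176 alone passed too, with 0 genes higher and 1558 at an unadjusted p under 0.05. Eif2ak4 (-0.54 ± 0.0730, adjusted p = 0.153), Tmem185b (-0.48 ± 0.0669, adjusted p = 0.153), the troponin gene Tnnc1 (0.34, 0.281) and Kbtbd3 (-0.39, 0.319) followed. Eif2ak4 and Tmem185b passed with median centring, where 0 genes were higher and 3 lower.

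Among the fixed lists, camera called 12 between genotypes over both times, each by a small shift, and 10 with Gpr176 itself left out of the lists. None of the 12 passed with an estimated correlation, and fry called 0 lists. By camera at the preset correlation, mitochondrial respiratory chain genes (median 0.0348, adjusted p = 0.000129), neighbouring hypothalamic neuron markers (0.0725, 0.000129), microglia markers (0.0835, 0.000956), ependymal and tanycyte markers (0.0464, 0.00193) and neuropeptides with their receptors (0.00548, 0.0308) were called higher in the knockout, each with an adjusted p of 0.475 with an estimated correlation. GABA and glutamate genes (-0.0585, 0.000302), channels (-0.0549, 0.000956), astrocyte markers (-0.0447, 0.0156), oligodendrocyte markers (-0.110, 0.0274), endothelial and mural markers (-0.0766, 0.0337) and the 3 sex-linked markers (-0.112, 0.0496) were called lower. With an estimated correlation their adjusted p was 0.475 for the GABA and glutamate genes, 0.498 for the channels and the sex-linked markers, 0.521 for the astrocyte, 0.696 for the oligodendrocyte and 0.588 for the endothelial markers. The SCN identity list, which holds the deleted gene, was called only with Gpr176 in it (-0.0554, adjusted p = 0.0205; adjusted p = 0.498 with an estimated correlation), and without it had a median of -0.0404 and an adjusted p of 0.157. The sex-linked list does not hold Gpr176. Its call, at an adjusted p of 0.0496 by camera, was lost as well in that setting, only through the adjustment over lists. Between 8 and 12 lists were called with 1 array left out. The respiratory chain, hypothalamic, microglia, ependymal, GABA and glutamate, and channel calls were kept without each array. The oligodendrocyte, astrocyte and endothelial calls were lost without wild type at CT6 B or CT18 A or knockout at CT6 B (8 lists called in each case), the endothelial call also without knockout at CT18 B (12 called), and the neuropeptide call without wild type at CT6 B or CT18 B or knockout at CT6 B (8, 10 and 8). The identity call was also lost without wild type at CT6 A or CT18 B or knockout at CT6 A (10 in each case), and the sex-linked call without any array but wild type at CT18 B and knockout at CT18 B. With no filter the neuropeptide and sex-linked calls were lost and the glucocorticoid-responsive genes were called, as they were without knockout at CT6 B or CT18 B. With the array axis as a covariate the oligodendrocyte, endothelial and sex-linked calls were lost. The median of the neuropeptide list changed sign to -0.0169 with median centring, and the glucocorticoid-responsive genes were also called with the values as deposited (adjusted p = 0.0344) and with median centring (0.0364). Camera called 4 lists at CT6 (3 with Gpr176 left out) and 8 at CT18, with adjusted p-values of 0.479 or more with an estimated correlation.

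Over the genes tested, 0 members of these 12 lists but Gpr176 passed in limma. At an unadjusted p under 0.05, 8 of 40 channel genes were lower and 1 higher, and 7 of 34 GABA and glutamate genes lower and 1 higher. Of 41 respiratory chain genes 4 were higher and 0 lower, a share under the 12.0% of all genes tested that reached this limit. Adjusted over the list alone, 7 neuropeptide genes were higher and 1 lower, including Nmu (0.45), Nms, a neuromedin of SCN neurons (0.29), Gal, the galanin precursor (0.26), and Avp (0.17). Oxt, oxytocin (0.32), and Th, tyrosine hydroxylase (0.26), passed in the same sense among the neighbouring hypothalamic markers. Further, 4 GABA and glutamate genes were lower, including the AMPA receptor subunit Gria3 (-0.17) and the GABA receptor subunit Gabra2 (-0.14). The knockout differences at CT6 and at CT18, which share no array, correlated across 12451 genes other than Gpr176 at r = 0.232 and Spearman's rho = 0.239. A one-sided exact permutation test gave p = 0.111, as 4 of 36 assignments reached that r, and the design allows no p under 0.0556.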

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

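The Gpr176 tests in this part were chosen only after the results were seen; the list tests were set in advance.

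The day-phase clock genes stood out because their day-night shift differed between genotypes by camera, with a median of 0.0770 (-0.756 in wild type and -0.661 in the knockout). Astrocyte markers stood out in the same way, with a median of -0.0992 (0.0535 in wild type and -0.0414 in the knockout). Both calls had an adjusted p of 0.905 with an estimated correlation. Outside the genes compared, 152 of 7064 probes with no gene name or several were called between CT18 and CT6 over both genotypes, 57 higher and 95 lower, with changes from -1.49 to 0.81. That was 2.15% of such probes against 6.33% of single-gene probes, in a fit of all probes without the level filter. The 2 sets of probes were not matched for level. Limma called 0 of the probes with no gene name or several between knockout and wild type, with 640 at an unadjusted p under 0.05.

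The Gpr176 probe kept a night rise of 0.44 log2 in the knockout, beside 0.46 in wild type. A constant non-specific signal in place of a transcript would give no rise, and the measured 0.443 argues against it as the whole signal. A scaling difference between the CT18 and CT6 arrays would vanish with median centring, and the rise was then 0.426 (adjusted p = 0.00393). What the remaining signal comes from, including binding of the probe to another rhythmic transcript, was not tested.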

How the results depend on the processing

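The values as deposited, the crossed block, the array axis and the lists with Gpr176 left out were tried only after the results were seen. So were the alternatives for the mean day-night difference and the lists without single arrays. Wild-type day-night genes numbered 466 over all probes, 1390 at an adjusted p under 0.1, 117 at 1.5-fold or more and 311 to 827 with 1 array left out. Knockout day-night genes numbered 590 with median centring, 495 over all probes, 1513 at an adjusted p under 0.1, 107 at 1.5-fold and 382 to 795 with 1 array left out. Over both genotypes 113 genes changed by 1.5-fold, and 1385 to 1803 passed with 1 array left out. At CT6, 2 genes differed between genotypes as deposited, with median centring and with the replicate block; at CT18, 3 did with median centring, at the 60th percentile and with trend and robust variances. Over both times there were 6 as deposited, 5 with median centring, 1 with no filter, 6 at the 60th percentile, 1 over all probes, 9 with trend and robust variances, 5 at an adjusted p under 0.1, 1 at 1.5-fold, 1 with the array axis and 1 to 4 with 1 array left out. The interaction called 0 genes in limma under each alternative run (605 at an unadjusted p under 0.05 in the chosen setting). Lists called with an estimated correlation numbered 1 in wild type and 0 in the knockout, over both genotypes, between genotypes and for the interaction; fry called 0 between genotypes and 0 for the interaction, the replicate block 0 and the array axis 1 for the interaction, and 0 to 5 interaction lists passed with 1 array left out. The mean signed day-night difference of the knockout was 95.1% of that of wild type as deposited and 95.9% with median centring. It was 100.9% with no filter, 100.5% with the mean of probes and 91.9% to 109.7% with 1 array left out. The letters A and B gave no uniform pairing of arrays (correlations of A deviations between groups -0.22 to 0.26). Wild type at CT18 ran against each other group (-0.22, -0.10 and -0.19). With the letter as a replicate block the counts were 765, 780, 2, 1, 4, 1946 and 0. Their order is wild type, knockout, CT6, CT18, both times, both genotypes and interaction. With the letters crossed in wild type at CT18 the counts in that order were 1180, 1279, 1, 1, 4, 2591 and 0. This crossing, added after the data were seen, follows the sign of those correlations, so the higher counts may come from that choice. The replicate block ended the sex-linked list's call between genotypes. Of 3515 alternatives for 324 gene and contrast pairs, 3371 were counted as unchanged, 123 lost the call and 21 gained it. Among pairs called in the chosen setting 0 turned, while a turned direction of an uncalled pair was counted as unchanged. Of the fits with 1 array left out, only those with the lowest and highest change per pair were counted. With 1 array left out, the lone array of its group is assumed to vary like the other groups. Background was not measured here, and the 7486 genes under the level filter were tested only in the alternative with no filter. The counts at stricter or looser thresholds follow from their construction; for the others the cause was not tested.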

Other observations

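The chance splits of gene counts reported in this part were planned; the splits for Gpr176 alone, the gene family counts, the leptomeningeal lists and the neighbour, array axis and tissue share tests were chosen only after the results were seen.

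Called genes were counted by family for the change between CT18 and CT6 over both genotypes. The families were picked after their values were seen, in part because members were among the largest changes, so the counts are descriptions without a test. Of all genes tested, 16.8% were called. The NR4A genes, Dusp1, Dusp6 and Gem are also in the immediate early list, Slc6a3 and Th in the neighbouring hypothalamic list, and some DnaJ genes in the heat shock and folding lists. Of 19 dual-specificity phosphatases, which remove phosphate from MAP kinases and other proteins, 8 fell and 4 rose, with Dusp4 (-2.21), Dusp1 (-0.96), Dusp10 (-0.68) and Dusp16 (-0.65) down and Dusp7 (0.38) up. Of 7 Ras-like and Rasd GTPases 3 fell and 2 rose, with Rasl11b (-2.27), Gem (-0.64) and Rasd2 (-0.49) against Rasd1 (1.56). Each of the 3 NR4A receptors fell. Of 19 sialyltransferases, which add sialic acid to glycans, 5 rose and 3 fell, with St8sia2 (0.64) against St8sia6 (-1.15) and St3gal1 (-0.99). Of 7 dopamine genes 2 rose and 2 fell, with the receptor Drd5 (0.72) and the transporter Slc6a3 (0.66) against Ddc (-0.18) and Slc18a2 (-0.19), which act in monoamine synthesis and vesicle storage. Ddc did not pass without wild type at CT6 A or knockout at CT18 B (highest adjusted p 0.0548). Slc18a2 kept its call only when the 1 array left out was wild type at CT18 A or knockout at CT6 B or CT18 B.

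Wnt pathway genes had 5 of 19 called, among them the ligand Wnt5a (-0.82), the antagonists Sfrp2 (-0.72) and Dkk2 (-0.71) and the receptor Fzd8 (0.98). Of the other families counted, 12 of 39 DnaJ cochaperones, 9 of 31 tRNA synthetases, 6 of 24 protocadherins, 45 of 229 solute carriers, 27 of 279 zinc finger Zfp genes and 3 of 39 small nucleolar RNAs were called.

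The 7 genes Efemp1, Fmod, Igf2, Ptgds, Slc13a4, Slc6a13 and Slc6a20a, which are abundant in the leptomeninges, were picked after their values were seen. Their mean log2 level was 8.00 and 8.74 in wild type at CT6, 9.02 and 7.83 in wild type at CT18, 9.07 and 8.23 in the knockout at CT6 and 7.85 and 7.88 in the knockout at CT18. Another list of leptomeningeal genes, 20 of them tested, gave 7.73 and 8.02, 8.15 and 7.72, 8.11 and 7.80, and 7.71 and 7.74 in the same order. In that list CT18 minus CT6 was 0.06 in wild type and -0.23 in the knockout, with a standard error over arrays of 0.213. For the 7 genes it was 0.06 and -0.78, with a standard error over arrays of 0.578.

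Other splits of the 8 arrays into 4 against 4 were counted over 34 splits, in a model that kept the other factor as a term and so left out the split along it. For time, 1 of them, the real one, reached 2191 genes and the highest other gave 0. The other splits left the time difference in the residual spread, which lowers their counts. As 1 of 34 is also the smallest share possible, these splits cannot exclude chance. For genotype this model called 2 genes, Gpr176 and Eif2ak4, while Tmem185b, which passed in the model with a mean for each group, stood at an adjusted p of 0.0540. The count of 2 was reached by 2 of the 34 splits, the highest other giving 2, so chance cannot be excluded for the count. For Gpr176 alone, 1 of the 34, the real one, gave a change as large as 1.30 log2, and the highest other gave 0.936. Each knockout array lay below each wild-type array, so the real split had to give the largest change. The count adds nothing to that separation.

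Eif2ak4, lower by 0.48 log2 in the knockout, is a neighbour of Gpr176, and a segment of another strain that stayed linked to the targeted locus may have lowered its signal. Of 22 tested neighbours, 4 (18.2%) had an unadjusted p under 0.05, a larger share than in 81.7% of random windows of the same size, which does not separate this segment from the rest of the genome. Fsip1, on the other side of Gpr176, stood at 0.18 (unadjusted p = 0.0107). With the score of each array on an axis that also separates replicates as a covariate, Eif2ak4 was at -0.458 instead of -0.485 (standard error 0.0516), and its adjusted p rose to 0.0553 with 1 residual degree of freedom fewer. An effect of the segment, of the deletion on its neighbour and of the lost receptor cannot be told apart here.

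The small list shifts between genotypes may come from an array axis or from a different share of neighbouring tissue in the pools. With the axis score as a covariate 75% of the 12 lists, with the identity list that rests on Gpr176 among them, stayed called, while the oligodendrocyte (adjusted p = 0.0590), endothelial (0.0950) and sex-linked calls (0.0952) were lost, which leaves that explanation open. Microglia (0.0785), ependymal (0.0648) and neighbouring hypothalamic markers (0.0974) were higher on average in the knockout, and oligodendrocyte (-0.100), astrocyte (-0.0606) and endothelial markers (-0.0726) lower. The gap between these 2 sets, 0.158 ± 0.0626, was 2.53 standard errors over arrays, but the directions were taken from the same arrays. A change of these cells in the knockout itself, uneven dissection and chance remain open.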
